A study of Mus musculus with 17 samples.

How the data were processed

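The libraries analysed came from mouse keratinocytes, with 6 RNA libraries (3 scrambled shRNA, 3 Msi2 shRNA), 6 footprint libraries (3 and 3) and 5 CLIP libraries that differ in RNase dilution (undiluted, 1 in 20 in 2 libraries, 1 in 50 and 1 in 75). Per the labels' protocols, cells received puromycin at 2 ug/ml 2 days after infection and for 2 days, and CLIP cells were irradiated with 200 mJ/cm2 of UVC. The deposited RNA and footprint tables hold counts of reads over the coding sequence of each of 20572 genes, made with TopHat and HTSeq on mm10 per the submitters' processing notes, which also name DESeq and give no versions. The deposited peak lists hold, per region, a signal, the total peak height over the 5 libraries, of 10 or more in every region, and the counts of reads of each library that overlap it, deposited as whole numbers. Height equalled the summed reads in 83.0% of regions and was lower in the others. Per the submitters' processing notes, CLIP reads were processed with cutadapt and Novoalign on mm10; the peak caller is not stated. The deposited description calls the regions clusters found over all 5 libraries and filtered, and every region has a read in 4 or 5 libraries.

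In the RNA table, reads assigned to no gene made up 32.3 to 35.2% of a library's total, reads of ambiguous assignment 0.175 to 0.228% and reads that aligned to several places 13.4 to 24.5%; these stayed out of library sizes and tests, and the footprint table holds no such lines. Gene positions came from a RefSeq table of GRCm38.p6, which matched 20446 of the symbols. No reference genome was used here, so the density of UAG in the peaks and a comparison matched on 3' UTR length were not computed.

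Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr with a minimum count of 10 and a total of 15, TMM factors, robust quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05). RNA and footprints were fitted apart, by group, without a replicate block. Translational efficiency was the interaction of assay and knockdown over all 12 libraries. Fold changes are knockdown (Msi2 shRNA) over control (scrambled shRNA), on the log2 scale with the standard error of the fit, and CPM values are TMM-scaled. Gene lists, 34 with 4 lists of markers of other cell types among them, were written before the data were examined. Lists with at least 5 measured members, the marker lists excepted, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry. Genes with a 3' UTR peak were compared with tested genes in neither peak list in the same way, and the 3 p-values were adjusted together. The share of list members with a peak was compared with genes of the same expression, taken as average footprint log2 CPM (10 bins, 10000 permutations). Exact intervals of count ratios, Wilson intervals of shares and the floor of 3 counts for a library with none (95%) cover counting error only.

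Named genes follow a rule written before the data were examined. They are Msi2 and Msi1; in each comparison the 10 largest increases and the 10 largest decreases among called genes with an average log2 CPM of at least 3 and, except for translational efficiency, no overlap between the groups; the 2 members of each list with the smallest p; the 10 genes with the most 3' UTR peaks; and the 5 higher and 5 lower genes with a peak and the smallest footprint p. Predicted genes are counted and not named, and some genes that the rule names are not reported here.

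The gene tests were tested on simulated data, with 200 genes changed by known fold changes at the libraries' own depths. Changes of 0.5, 1 and 2 on the log2 scale were recovered in 32.8, 85.1 and 95.5% of genes for RNA (11117 genes), 22.4, 74.6 and 98.5% for footprints (8969 genes) and 8.96, 40.3 and 86.4% for translational efficiency (10821 genes), with 6, 6 and 7 false calls. The simulation changed 200 genes, while 4866 were called in the real RNA data and 1448 in footprints, and the adjustment depends on that number. The recovery rates are thus not those of the real RNA and footprint tests. Depth is given per library at the start of the report, and the shallowest footprint library holds 512256 counts. Alternatives planned before the data were examined were DESeq2 1.42.0 (its size factors and its Wald test), upper-quartile factors, limma-voom with quality weights, no filter, a filter of 10 CPM in 3 libraries, a replicate block, a fold change minimum of 1, 1 fit over all 12 libraries, other peak sets and matched comparison genes, and each library left out in turn. Removal of each library's trend with genomic span (loess, span 0.5), comparison genes of the same span, leaving out the shallowest footprint library of each group, and a block joining RNA and footprint libraries of the same group and number were added after the data were seen. Libraries were also split in all 10 possible ways within RNA and within footprints, and in 100 of 200 ways for translational efficiency. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.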

Results

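The study asked which RNAs Musashi-2 (Msi2), an RNA-binding protein that acts on 3' UTRs, binds and changes in mouse keratinocytes, and how this bears on the movement of epithelial cells. The cells were a keratinocyte culture from newborn C57BL/6 skin that had become immortal without an introduced gene; it was grown on inactivated fibroblast feeder cells for the first 3 passages and on plain dishes afterwards. A lentivirus carried either a short hairpin RNA against Msi2 (knockdown) or one with a scrambled sequence (control), and infected cells were selected with 2 ug/ml of puromycin for 2 days. RNA abundance was measured by sequencing of polyadenylated RNA in 3 control and 3 knockdown libraries. Ribosome footprints, the RNA pieces that ribosomes protect from nuclease, were sequenced in another 3 control and 3 knockdown libraries. Msi2 binding sites were mapped in 5 libraries of HITS-CLIP, in which ultraviolet light fixes the protein to the RNA it touches before both are recovered with an antibody. The gene counts of the RNA libraries came to 19876752, 24931967 and 11291571 in the control and 9221566, 12107068 and 26785876 in the knockdown. The footprint libraries were smaller, with 2196405, 2959625 and 702602 in the control and 2069440, 512256 and 998028 in the knockdown. The CLIP libraries held 6608, 44753, 50864, 61629 and 53712 reads in the listed peaks. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

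Msi2 itself was examined first, in every library. Its ribosome footprints fell from 17.3 ± 0.496 CPM in the control to 3.21 ± 2.79 CPM in the knockdown (CPM, counts scaled to library size; mean ± SD, n = 3), a log2 fold change of -2.08 ± 0.41 (SE). The adjusted p of edgeR's quasi-likelihood test was 0.000285. Single control libraries held 17.1, 16.9 and 17.9 CPM, and the knockdown libraries 4.55, 0 and 5.07 CPM. The count of 0 was in the smallest library, where 3 counts correspond to 6.02 CPM, so it allows a level of up to that value (counting error only). Msi2 RNA over the coding sequence was 7.35 ± 1.29 CPM in the control and 6.00 ± 0.790 CPM in the knockdown, with a log2 fold change of -0.29 ± 0.21 (adjusted p = 0.283), a difference that did not pass the test. The RNA values rest on 63 to 152 reads per library. The footprint-to-RNA ratio of Msi2 had a log2 fold change of -1.79 ± 0.48 (adjusted p = 0.117). The gene lies on chromosome 11, 88339382 to 88718306 (mm10). Its relative Msi1 was lowly expressed, at 0.873 ± 0.318 CPM of RNA in the control and 1.58 ± 0.539 CPM in the knockdown (adjusted p = 0.0961), and its footprints summed to 7 and 4 counts, too few to test. Neither gene has a peak in the 3' UTR list.

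**Figure D1:**
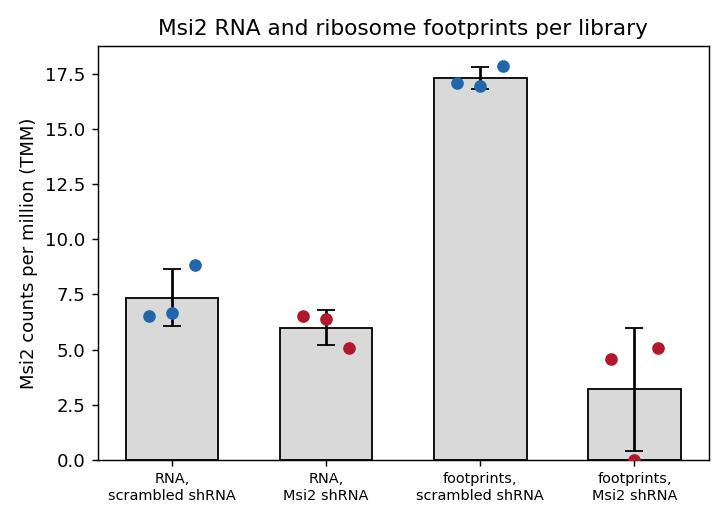
Msi2 RNA and ribosome footprints, in TMM-scaled CPM (vertical axis), in each library (points) of the control and knockdown groups, with the group mean (bar) and SD (error bar, n = 3). The 3 knockdown footprint libraries lie at 0 to 5.07 CPM, all below the control libraries at 16.9 to 17.9 CPM, while the RNA values of the groups lie close to each other.

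RNA abundance was compared between knockdown and control to find the genes whose RNA changed when Msi2 was lowered. Among called genes whose groups did not overlap and whose average was at least 3 on the log2 CPM scale, the largest increase was that of Cdh2, which encodes the adhesion protein N-cadherin, from 2.56 ± 1.19 to 33.4 ± 4.48 CPM (log2 fold change 3.64 ± 0.23, adjusted p = 2.45e-08; chromosome 18, 16588877 to 16809246). Itga2, the collagen-binding integrin alpha 2, rose by 2.69 ± 0.34, the matrix glycoprotein Thbs1 by 2.45 ± 0.15, the spectrin Sptbn1 by 2.13 ± 0.16 and the proteoglycan Vcan by 2.12 ± 0.14 on the log2 scale. The 10 largest increases by this rule also held St5 (2.40), Zfp57 (2.13), Emp3 (2.01) and the cytokine subunit gene Il23a (1.98). Among the genes that fell, Lgals7, the galectin of stratified epithelia, went from 1225 ± 211 to 166 ± 3.16 CPM (-2.88 ± 0.14, adjusted p = 1.95e-09; chromosome 7, 28863796 to 28866285). The fatty acid carrier Fabp4 (-3.59 ± 0.20) and the protease inhibitor Serpinb1a (-3.59 ± 0.22) fell furthest, followed by the keratin Krt15 (-3.41 ± 0.76, adjusted p = 0.0209) and the stefin Stfa3 (-3.11 ± 0.33). The 10 largest decreases also held Bpifc (-3.05), the mitochondrial folate enzyme Aldh1l2 (-2.98), the pseudokinase Trib3 (-2.97), the hormone Stc2 (-2.93) and the protease Tmprss4 (-2.81).

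Of 11117 genes tested, 2449 were higher and 2417 lower in the knockdown at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of these, 571 and 370 changed by at least 1 on the log2 scale. The libraries of the 2 groups did not overlap for 52.9% of the genes, against 10% by chance. Leaving out 1 library ended the calls of some genes with wide spread. These were Trib3 without control replicate 3 (adjusted p = 0.0675), knockdown replicate 1 (adjusted p = 0.0944) or knockdown replicate 3 (adjusted p = 0.0643), Krt15 without control replicate 2 (adjusted p = 0.0690) or knockdown replicate 1 (adjusted p = 0.0774), Aldh1l2 without control replicate 3 (adjusted p = 0.0560) or knockdown replicate 1 (adjusted p = 0.0582), and Stc2 without control replicate 3 (adjusted p = 0.0581). Stfa3 has near-identical copies among the stefin genes, so its counts are uncertain.

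Gene lists fixed before the data were examined were compared as groups, by counts of members past the gene test and by camera, a test of a list against all other genes. Of 29 lists tested in RNA, 11 were higher and 6 lower at an adjusted p under 0.05 with a preset correlation between genes of 0.01. With the correlation estimated from these libraries none passed (smallest adjusted p = 0.102), although 6 had an unadjusted p under 0.05, and with fry, which tests whether a list moves as a whole, 14 passed. Counts of members adjusted over the list alone were the same as over all genes for 25 of the 34 lists and are given where they differed. In the focal adhesion and integrin list, 21 of 29 rose and 1 fell, or 22 and 1 adjusted over the list alone (median log2 fold change 0.46, adjusted p = 4.59e-08, and adjusted p = 0.152 with an estimated correlation). Flna, which cross-links actin, was among those that rose (1.43 ± 0.15). In the list of secreted matrix proteins and proteases, 16 of 21 rose and 2 fell (median 0.68, adjusted p = 3.21e-07, and adjusted p = 0.152 with an estimated correlation). Thbs1 and the collagenase Mmp1b (2.96 ± 0.37) came first by p. Mmp1b has a close copy, Mmp1a, so its counts are uncertain. Of the TGF-beta pathway and its targets, 11 of 21 rose and 0 fell, or 12 and 0 adjusted over the list alone (median 0.32, adjusted p = 0.000266, and adjusted p = 0.152 with an estimated correlation). Ctgf, a matricellular growth factor that is also a YAP target, rose by 1.25 ± 0.11 and the activin subunit Inhba by 2.00 ± 0.23. Of the YAP targets, 10 of 16 rose and 1 fell (median 0.70, adjusted p = 0.000168, and adjusted p = 0.229 with an estimated correlation). Cyr61 (1.46 ± 0.16) was among them. In the mesenchymal transition list, 6 of 14 rose and 2 fell (median 0.41, adjusted p = 0.00726, and adjusted p = 0.229 with an estimated correlation). The hyaluronan receptor Cd44 (0.71 ± 0.11) followed Cdh2 there.

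The basal keratinocyte list also rose as a group, as 10 of 16 rose and 4 fell (median 0.55, adjusted p = 0.00340, and adjusted p = 0.304 with an estimated correlation). The laminin-332 chains Lama3 (1.40 ± 0.14) and Lamb3 (0.95 ± 0.12), which anchor the epidermis to its basement membrane, had the smallest p-values. The 4 members that fell, named after their values were seen, were the keratins Krt5 (-0.62), Krt14 (-0.39) and Krt15 and the cadherin Cdh3 (-0.40). Among cytokines and chemokines, 13 of 17 rose and 4 fell (median 1.03, adjusted p = 9.62e-06, and adjusted p = 0.102 with an estimated correlation). The growth factor Csf3 (1.91 ± 0.13) and the NF-kB inhibitor Tnfaip3 (1.91 ± 0.15) came first by p. The 4 that fell, named after their values were seen, were Il33 (-3.10), Tslp (-1.73), Il18 (-1.61) and Ccl20 (-1.29), cytokines that epithelia release. Of the RNA-binding proteins and 3' UTR regulators, 16 of 32 rose and 0 fell, or 17 and 0 adjusted over the list alone (median 0.47, adjusted p = 0.000948, and adjusted p = 0.229 with an estimated correlation). The Argonaute gene Eif2c2 (0.92 ± 0.14) and its partner Tnrc6a (0.80 ± 0.13) came first by p. Of the immediate early and AP-1 genes, 8 of 20 rose and 1 fell (median 0.57, adjusted p = 0.0134, and adjusted p = 0.536 with an estimated correlation). Jun (1.26 ± 0.17) and the phosphatase Dusp5 (1.05 ± 0.14) came first by p. In the Notch pathway, 6 of 14 rose and 2 fell (median 0.37, adjusted p = 0.0313, and adjusted p = 0.560 with an estimated correlation). The ligands Dll1 (1.34 ± 0.13) and Jag1 (1.18 ± 0.17) came first by p. Of the Musashi targets named in the literature, 7 of 16 rose and 1 fell (median 0.27, adjusted p = 0.0293, and adjusted p = 0.536 with an estimated correlation). The leucine zipper gene Tsc22d3 was down (-0.97 ± 0.15) and Jag1 up. The Notch list did not pass without control replicate 2 (adjusted p = 0.0646) or knockdown replicate 2 (adjusted p = 0.0979), nor did the Musashi targets (adjusted p = 0.0764 and 0.0748). With the span trend removed the Musashi targets did not pass (adjusted p = 0.0844), and with fry the Notch and immediate early lists (adjusted p = 0.0586 each) and the ribosomal proteins below (adjusted p = 0.257) did not.

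The strongest decrease of a list was that of the ATF4 integrated stress response, the programme of amino acid synthesis and uptake genes that ATF4 switches on, in which 0 of 23 rose and 20 fell (median -1.20, adjusted p = 2.99e-18, and adjusted p = 0.229 with an estimated correlation). Cth, which makes cysteine, fell by 1.70 ± 0.14 and asparagine synthetase Asns by 1.59 ± 0.14, while Atf4 itself had a log2 fold change of -0.58 ± 0.12 (adjusted p = 0.00130). Of the respiratory chain genes, 0 of 30 rose and 26 fell (median -0.63, adjusted p = 9.56e-10, and adjusted p = 0.427 with an estimated correlation). The complex I subunits Ndufv1 (-0.77 ± 0.11) and Ndufs7 (-0.79 ± 0.12) came first by p. In hypoxia and glycolysis, 0 of 22 rose and 14 fell (median -0.59, adjusted p = 4.03e-06, and adjusted p = 0.102 with an estimated correlation). The glycolytic enzyme Pfkp (-1.36 ± 0.13) and Ndrg1 (-1.10 ± 0.14) came first by p. Of the differentiated keratinocyte genes, 1 of 18 rose and 11 fell (median -0.75, adjusted p = 4.03e-06, and adjusted p = 0.195 with an estimated correlation). They include the protease inhibitor Spink5 (-1.61 ± 0.13) and the cornified envelope enzyme Tgm3 (-2.63 ± 0.28). Among NRF2 targets, 1 of 19 rose and 10 fell (median -0.36, adjusted p = 0.00485, and adjusted p = 0.229 with an estimated correlation). The glutathione transferase Gsta4 was down (-1.30 ± 0.13) and thioredoxin reductase Txnrd1 up (0.88 ± 0.12). Of the cytosolic ribosomal proteins, 5 of 75 rose and 20 fell, or 4 and 12 adjusted over the list alone (median -0.20, adjusted p = 0.00921, and adjusted p = 0.765 with an estimated correlation). Rpl5 (-0.58 ± 0.13) and Rpl3 (-0.52 ± 0.13) came first by p. This list did not pass without control replicate 2 (adjusted p = 0.317) or knockdown replicate 1 (adjusted p = 0.0633), and its median was -0.021, with the test turned upwards (adjusted p = 0.902), once a trend of the libraries with gene span was removed. The ribosomal protein genes share reads with many pseudogenes, and the share of reads that aligned to several places was 21.8 ± 2.45% in the knockdown and 15.2 ± 2.01% in the control RNA libraries (SD, n = 3, two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give).

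The other 12 lists did not pass in RNA, with adjusted p-values from 0.0840 to 0.866. In the stress keratin and alarmin list, 4 of 12 rose and 6 fell, with Krt6b down (-2.64 ± 0.14) and the calprotectin subunit S100a8 up (1.51 ± 0.20). Of the junction genes, 5 of 22 rose and 6 fell, of the cell cycle genes, 9 of 30 rose and 4 fell, of the p53 targets, 7 of 19 rose and 3 fell, and of the actin and migration genes, 6 of 29 rose and 3 fell, or 4 and 3 adjusted over the list alone. In the simple epithelial keratins, 2 of 5 rose and 1 fell, and in the Wnt list, 4 of 17 rose and 2 fell, or 3 and 2 adjusted over the list alone. Of the unfolded protein response genes, 2 of 18 rose and 3 fell, or 2 and 2 adjusted over the list alone, of the cholesterol synthesis genes, 6 of 24 rose and 5 fell, of the translation factors, 7 of 32 rose and 10 fell, or 7 and 13 adjusted over the list alone, of the interferon response genes, 3 of 8 rose and 1 fell, and of the stem cell and hair follicle genes, 2 of 15 rose and 2 fell. Median, mean and test differed in sign for the interferon (median -0.0080, mean 0.16, test upward), cholesterol (median -0.10, mean 0.02, test upward) and stem cell lists (median 0.07, mean -0.12, test upward). Replication-dependent histones, whose RNAs lack the poly(A) tail used for selection, had 4 measured members and were not tested in RNA. Markers of other cell types were low in both groups. The fibroblast collagens Col1a2 and Col3a1 had no reads and Col1a1 went from 0.258 to 0.360 CPM, against 7068 to 4554 CPM for Krt5. Fstl1, a fibroblast marker that other cells also express, stood at 10.6 and 10.5 CPM. Of the 3 measured fibroblast markers 1 rose, or 2 adjusted over the list alone (Pdgfra and Twist2). The one called over all genes was Pdgfra (0.813 to 1.87 CPM, adjusted p = 0.0258), whose call ended without control replicate 2 (adjusted p = 0.0555) or 3 (adjusted p = 0.0825) and without knockdown replicate 2 (adjusted p = 0.0616) or 3 (adjusted p = 0.116), and with DESeq2 (adjusted p = 0.0607). The highest melanocyte marker was Pmel (1.52 to 1.83 CPM, adjusted p = 0.761). Of the immune markers the highest was Cd68, at 16.9 and 9.82 CPM (adjusted p = 0.00323), and of the endothelial and muscle markers Kdr, at 1.57 and 3.72 CPM (adjusted p = 0.00590).

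Ribosome footprints were compared to ask which changes reached the RNA that ribosomes were reading. The largest changes are given by the same rule as for RNA. Cdh2 rose from 6.58 ± 5.10 to 80.6 ± 3.94 CPM (log2 fold change 3.39 ± 0.28, adjusted p = 1.53e-10) and Itga2 by 2.78 ± 0.19. Plec, the plectin that ties keratin filaments to hemidesmosomes, rose by 2.04 ± 0.15 and Sptbn1 by 2.14 ± 0.17. The G protein regulator Rgs16 had 2 counts in the control libraries together and 64 in the knockdown, a ratio of 55.1-fold (95% counting interval 14.7 to 465, exact). St5 (2.88), Gpsm1 (2.40), Dynap (2.20) and Emp3 (2.11) were also among the 10 largest increases. On the other side, 110 control and 3 knockdown counts gave Tgm3 a ratio of 21.3-fold (95% counting interval 7.09 to 105, exact) in favour of the control. The gap junction gene Gjb2, with 75 and 2 counts, was lower in the knockdown by 21.8-fold (95% counting interval 5.82 to 183, exact), and the calpain subunit gene Capns2, with 76 and 2, by 22.1-fold (95% counting interval 5.90 to 185, exact). Further decreases were those of Phyhd1 (-3.90), Krt15 (-3.78 ± 0.42), Serpinb1a (-3.59 ± 0.34), the cornified envelope protein gene Csta (-3.49), Bpifc (-3.25), the thioesterase gene Acot2 (-3.20) and Trib3 (-3.16, adjusted p = 0.0487). Of 8969 genes tested, 786 were higher and 662 lower at an adjusted p under 0.05 (edgeR), and 181 and 230 of them changed by at least 1 on the log2 scale. The groups did not overlap for 31.4% of the genes, against 10% by chance. DESeq2's Wald test called 808 genes. Without control replicate 1 edgeR called 907, without knockdown replicate 1 it called 842, and without knockdown replicate 3 it called 849. Trib3 lost its call without control replicate 3 (adjusted p = 0.116) and without knockdown replicate 1 (adjusted p = 0.187), 2 (adjusted p = 0.0627) or 3 (adjusted p = 0.192), as well as without a filter (adjusted p = 0.0568), with the span trend removed (adjusted p = 0.0561) and without the shallowest footprint library of each group (adjusted p = 0.174). In 1 fit over all 12 libraries Krt15 (adjusted p = 0.0654) and Acot2 (adjusted p = 0.122) were not called.

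Of 29 lists tested in footprints, 9 were higher and 8 lower with the preset correlation, none passed with an estimated correlation (smallest adjusted p = 0.15, with 7 lists at an unadjusted p under 0.05) and 15 passed with fry. In the focal adhesion and integrin list, 16 of 28 rose and 0 fell, or 19 and 0 adjusted over the list alone (median 0.50, adjusted p = 4.22e-13, and adjusted p = 0.15 with an estimated correlation). Itga2 was among those that rose. In the matrix and protease list, 12 of 20 rose and 1 fell, or 14 and 3 adjusted over the list alone (median 0.64, adjusted p = 1.56e-10, and adjusted p = 0.15 with an estimated correlation). Thbs1 (2.02 ± 0.14) and the laminin Lama5 (1.28 ± 0.14) came first by p. In the mesenchymal list, 7 of 11 rose and 0 fell, or 9 and 1 adjusted over the list alone (median 0.51, adjusted p = 2.52e-05, and adjusted p = 0.154 with an estimated correlation), and fibronectin Fn1 (0.59 ± 0.14) stood next to Cdh2. In the cytokine list, 8 of 10 rose and 1 fell (median 1.01, adjusted p = 2.26e-10, and adjusted p = 0.15 with an estimated correlation). Csf3 (2.02 ± 0.16) and the prostaglandin synthase Ptgs2 (1.24 ± 0.14) came first by p. In the basal keratinocyte list, 10 of 16 rose and 2 fell, or 10 and 3 adjusted over the list alone (median 0.52, adjusted p = 0.00131, and adjusted p = 0.355 with an estimated correlation). Lama3 was up (1.22 ± 0.14) and Krt15 down. Of the YAP targets, 6 of 15 rose and 1 fell, or 7 and 1 adjusted over the list alone (median 0.33, adjusted p = 0.000565, and adjusted p = 0.154 with an estimated correlation). The receptor Axl (1.07 ± 0.13) and Cyr61 (1.29 ± 0.17) came first by p. Of the TGF-beta list, 5 of 20 rose and 0 fell, or 7 and 1 adjusted over the list alone (median 0.18, adjusted p = 0.0178, and adjusted p = 0.243 with an estimated correlation). Ctgf (1.07 ± 0.15) and Id1 (1.04 ± 0.18) came first by p. Of the cell cycle genes, 5 of 30 rose and 0 fell (median 0.22, adjusted p = 0.0178, and adjusted p = 0.354 with an estimated correlation). Mki67 (0.92 ± 0.15) was among them. Of the ribosomal proteins, 9 of 74 rose and 0 fell (median 0.12, adjusted p = 0.0210, and adjusted p = 0.702 with an estimated correlation). Rpl23 (0.67 ± 0.13) and Rplp2 (0.60 ± 0.14) came first by p.

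Footprints of the ATF4 list were lower, as 0 of 21 rose and 18 fell, or 0 and 20 adjusted over the list alone (median -1.12, adjusted p = 1.83e-25, and adjusted p = 0.154 with an estimated correlation). The transcription factor Atf5 fell by 1.93 ± 0.20 and seryl-tRNA synthetase Sars by 1.22 ± 0.14 on the log2 scale, and Atf4 had a log2 fold change of -1.26 ± 0.16 (adjusted p = 2.86e-07). Of the replication-dependent histones, 0 of 44 rose and 20 fell, or 0 and 24 adjusted over the list alone (median -0.62, adjusted p = 2.58e-11, and adjusted p = 0.318 with an estimated correlation). Hist1h2bg (-1.26 ± 0.15) and the linker histone Hist1h1e (-0.99 ± 0.13) came first by p. Histone genes are near-identical copies, so counts of single members are uncertain. In hypoxia and glycolysis, 0 of 20 rose and 10 fell, or 0 and 12 adjusted over the list alone (median -0.47, adjusted p = 2.93e-06, and adjusted p = 0.174 with an estimated correlation). Pfkp (-1.14 ± 0.16) and Ndrg1 (-1.17 ± 0.17) came first by p. Of the differentiated keratinocyte genes, 0 of 14 rose and 7 fell (median -0.62, adjusted p = 7.16e-05, and adjusted p = 0.251 with an estimated correlation). Spink5 stood at -1.63 ± 0.14. Of the junction genes, 2 of 22 rose and 9 fell, or 3 and 10 adjusted over the list alone (median -0.31, adjusted p = 0.0163, and adjusted p = 0.355 with an estimated correlation). The desmosomal cadherin Dsc2 was down (-1.11 ± 0.14) and the catenin Ctnnd1 up (0.58 ± 0.13). Of the NRF2 targets, 1 of 15 rose and 5 fell, or 2 and 8 adjusted over the list alone (median -0.35, adjusted p = 0.0204, and adjusted p = 0.190 with an estimated correlation). The cystine transporter Slc7a11 was down (-1.22 ± 0.19) and Txnrd1 up (0.86 ± 0.14). Of the respiratory chain genes, 0 of 30 rose and 4 fell, or 0 and 6 adjusted over the list alone (median -0.19, adjusted p = 0.0101, and adjusted p = 0.355 with an estimated correlation). Uqcrc1 (-0.60 ± 0.13) was among them. Of the stress keratins and alarmins, 2 of 10 rose and 5 fell (median -0.34, adjusted p = 0.0350, and adjusted p = 0.318 with an estimated correlation). Krt6b stood at -2.66 ± 0.24 and S100a8 at 1.62 ± 0.22. Leaving out 1 library ended some list calls, namely that of the TGF-beta list without control replicate 1 (adjusted p = 0.0602), of ribosomal proteins without control replicate 1 (adjusted p = 0.262) or knockdown replicate 1 (adjusted p = 0.472), and of the respiratory chain without knockdown replicate 3 (adjusted p = 0.0601). The cell cycle list failed without control replicate 3 (adjusted p = 0.0841) or knockdown replicate 1 (adjusted p = 0.0565), and the stress keratins without control replicate 2 (adjusted p = 0.0637) or 3 (adjusted p = 0.0803) or knockdown replicate 2 (adjusted p = 0.0515). Without the shallowest footprint library of each group neither of these lists passed (adjusted p = 0.0699 and 0.108), nor did the stress keratins with the span trend removed (adjusted p = 0.0837). With fry the basal keratinocyte (adjusted p = 0.0510), histone (adjusted p = 0.0617), stress keratin (adjusted p = 0.0624) and ribosomal protein lists (adjusted p = 0.328) did not pass.

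The other 12 tested lists did not pass in footprints, with adjusted p-values from 0.0939 to 0.810. Of the actin and migration genes, 7 of 29 rose and 0 fell, with non-muscle myosin Myh9 (0.67 ± 0.13) and cofilin Cfl1 (0.59 ± 0.13) first. Of the Notch genes, 4 of 14 rose and 0 fell, or 5 and 0 adjusted over the list alone, of the Wnt genes, 1 of 13 rose and 0 fell, of the p53 targets, 3 of 19 rose and 2 fell, or 6 and 3 adjusted over the list alone, and of the Musashi targets, 2 of 15 rose and 1 fell, or 2 and 3 adjusted over the list alone. Of the immediate early genes, 6 of 19 rose and 1 fell, or 7 and 3 adjusted over the list alone, of the unfolded protein response genes, 2 of 18 rose and 2 fell, or 3 and 2 adjusted over the list alone, of the cholesterol genes, 1 of 23 rose and 0 fell, and of the interferon genes, 0 of 5 rose and 0 fell. Of the translation factors, 6 of 31 rose and 4 fell, or 9 and 4 adjusted over the list alone, with the translation repressor Eif4ebp1 down (-1.36 ± 0.15). Of the RNA-binding proteins, 2 of 29 rose and 1 fell, where Msi2 was the member that fell, and of the stem cell and hair follicle genes, 2 of 12 rose and 3 fell. Median and mean differed in sign for the Musashi targets (0.08 and -0.02, test upward) and the unfolded protein response (0.13 and -0.0032, test upward). In the simple epithelial keratins, with 4 members and no test of the list, 2 of 4 rose and 0 fell.

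**Figure D2:**
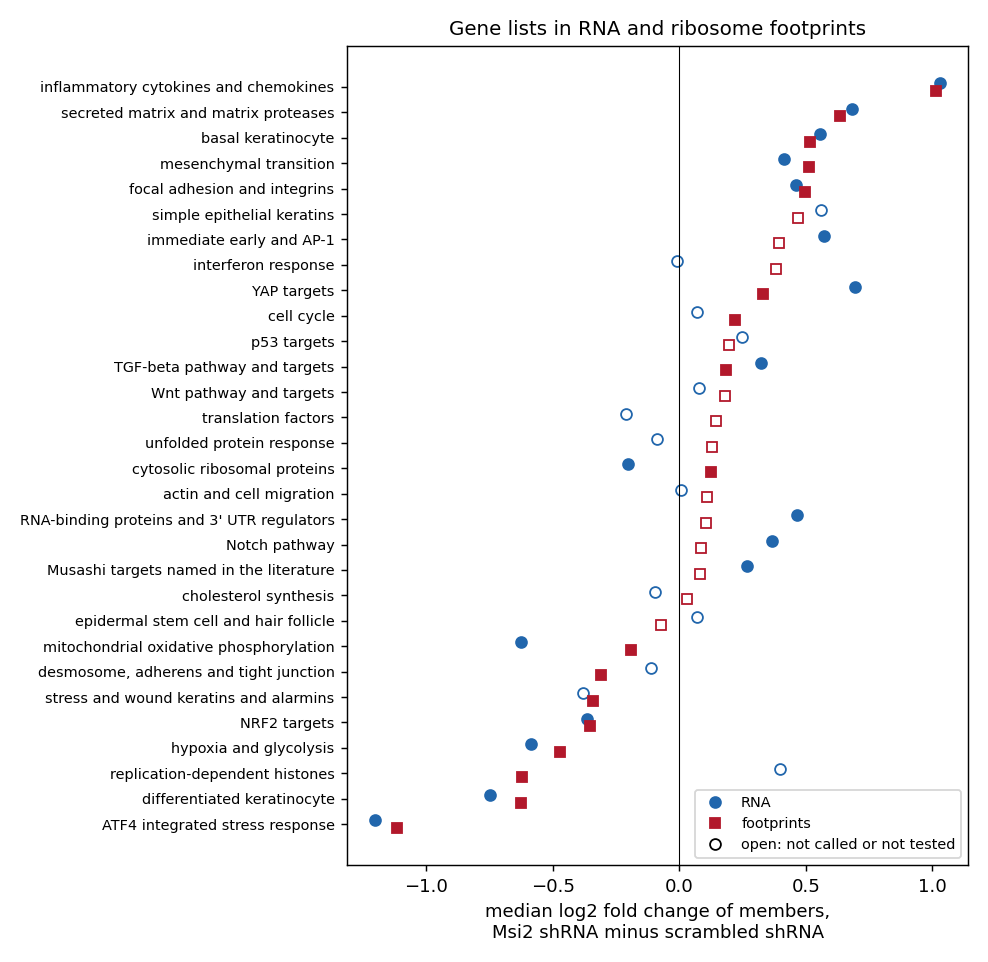
Median log2 fold change (horizontal axis, knockdown minus control) of the measured members of each gene list, the 4 lists of markers of other cell types left out, in RNA and in ribosome footprints. Among the lists drawn, the ATF4 list lies furthest to the left, with medians of -1.20 in RNA and -1.12 in footprints, and the cytokine list furthest to the right, at 1.03 and 1.01.

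RNA and footprint changes were then set side by side, since both would change alike if footprints followed RNA abundance. Across 8918 genes tested in both, the log2 fold changes had a Pearson correlation of 0.741 and a Spearman correlation of 0.656; genes are not independent replicates, so no p is given. Of these genes, 594 were higher in both, where independent lists would share 173, and 548 were lower in both, against 157. Opposite calls were found for 6 genes, against 333. Cdh2, Itga2, St5, Sptbn1 and Emp3 were among the 10 largest increases of both comparisons, and Krt15, Serpinb1a, Bpifc and Trib3 among the 10 largest decreases of both. No library entered both comparisons. Deviations of same-numbered RNA and footprint libraries from their groups correlated at 0.0039 to 0.232. These libraries may share a source, which the labels do not state, so the comparisons may not be independent.

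**Figure D3:**
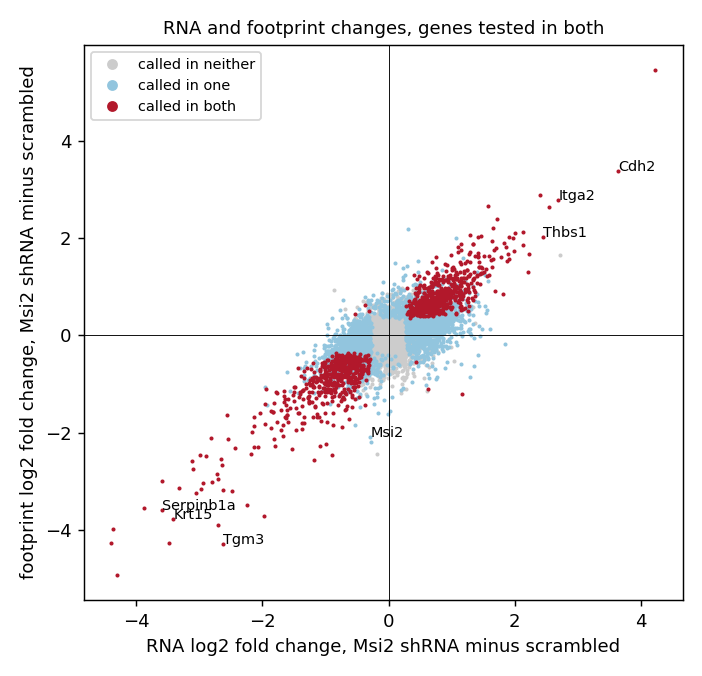
Log2 fold change of each gene (knockdown minus control) in RNA (horizontal axis) and in ribosome footprints (vertical axis), for 8918 genes tested in both. Most points lie along the rising diagonal (Pearson 0.741), and Msi2 lies below it, at -0.29 in RNA and -2.08 in footprints.

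Translational efficiency, the ratio of footprints to RNA, was tested as the interaction of assay and knockdown in 1 model over all 12 libraries. The increases included the ribosomal protein gene Rpl23 (1.02 ± 0.19, adjusted p = 0.0208), the elongation factor Eef1b2 (0.98 ± 0.20), the initiation factor Eif1ax (1.00 ± 0.22) and the metalloprotease inhibitor Timp2 (0.91 ± 0.19). Dnajc24 (1.28), Churc1 (1.19), Timmdc1 (1.13), Ube2v1 (1.01), Gcsh (0.99) and Tmem238 (0.90) were the others of the 10 largest. The decreases included Lpp, a focal adhesion protein, at -1.99 ± 0.41 (adjusted p = 0.0336), whose RNA had a log2 fold change of 1.85 ± 0.52 while its footprints stood at -0.18 ± 0.16. Zfp652 (-1.63), the linker histone Hist1h1c (-1.30), the kinase Mapk6 (-1.30), Zfp266 (-1.19), Emc1 (-1.12) and Rbm28 (-0.97) were lower as well. Msi2 (adjusted p = 0.117) and Atf4 (-0.66 ± 0.21, adjusted p = 0.172) did not pass in this fit, which uses no replicate block. Msi2 did pass in a fit, added after the data were seen, with a block joining RNA and footprint libraries of the same group and number. Of 10821 genes, 14 had a higher and 8 a lower ratio at an adjusted p under 0.05 (edgeR), and 1300 had an unadjusted p under 0.05. A replicate block left 3 calls, while the block joining RNA and footprint libraries gave 353 (246 higher, 107 lower). The count of called genes thus depends on how the replicate numbers are treated. The split of higher and lower calls was 11 and 13 with DESeq2's size factors, 5 and 13 with upper-quartile factors, 46 and 78 without a filter and 3 and 11 for genes of at least 10 CPM. Higher calls led with DESeq2 (69 and 43), with limma-voom (68 and 18) and with the trend of the libraries with gene span removed (29 and 12). Leaving out 1 library changed the count to 5, 13 and 243 without RNA control replicates 1, 2 and 3, and 8, 8 and 0 without RNA knockdown replicates 1, 2 and 3. Without footprint control replicates 1 and 3 it was 0 and 9, and without footprint knockdown replicates 1 and 3 it was 2 and 1.

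As groups, ribosomal proteins and the respiratory chain were higher in translational efficiency. The ribosomal proteins had a median of 0.33 (adjusted p = 8.78e-14, and adjusted p = 0.513 with an estimated correlation), although 1 of 75 rose and 0 fell, or 14 and 1 adjusted over the list alone; Rps9 followed Rpl23 at 0.81 ± 0.19 (adjusted p = 0.0535). The respiratory chain genes had a median of 0.39 (adjusted p = 4.53e-11, and adjusted p = 0.513 with an estimated correlation). Of them 0 of 30 rose and 0 fell, or 4 and 0 adjusted over the list alone, and Cox4i1 (0.75 ± 0.19, adjusted p = 0.0888) had the smallest p. Both lists had lower RNA medians in the knockdown. That of the ribosomal proteins was -0.20, but -0.021 with the span trend removed, and the list did not pass in RNA with fry. The share of reads aligning to several places, 21.8% against 15.2%, moved with the same groups. The translation factors had a median of 0.21 (adjusted p = 0.00134, and adjusted p = 0.513 with an estimated correlation); 1 of 32 rose and 0 fell, or 3 and 0 adjusted over the list alone, the called one being Eef1b2. Lower ratios were found for 3 lists. One was the histones (median -0.62, adjusted p = 5.60e-05, and adjusted p = 0.513 with an estimated correlation; 0 of 44 rose and 1 fell, or 0 and 3 adjusted over the list alone), for which this is no test of translational efficiency. Poly(A) selection left 4 of the 50 listed histones measured in RNA, and the median was that of their footprints. With the 8 members that had a group at 0 set at 3 counts over the group, or left out where both groups were at or below that (6 members), it was -0.60. The Musashi targets named in the literature had a median of -0.18 (adjusted p = 0.00233, and adjusted p = 0.513 with an estimated correlation); 0 of 16 rose and 0 fell, or 0 and 1 adjusted over the list alone, and Jag1 stood at -0.62 ± 0.23 (adjusted p = 0.256). The RNA-binding proteins had a median of -0.21 (adjusted p = 0.00233, and adjusted p = 0.513 with an estimated correlation), and 0 of 30 rose and 0 fell, or 0 and 3 adjusted over the list alone. Msi2 and the deadenylase Cnot6 (-1.02 ± 0.28, adjusted p = 0.133) had the smallest p-values among them. The other 24 of the 30 lists had adjusted p-values from 0.0527 to 0.850, and their members, Timp2 excepted, were not called over all genes. With an estimated correlation no list passed (1 had an unadjusted p under 0.05), nor with fry (6 had one). Median, mean and test differed in sign for the ATF4 list (median 0.19, mean -0.26, test upward), focal adhesion (0.0049, -0.04, downward), p53 targets (0.02, -0.14, downward) and cytokines (0.08, 0.16, downward).

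The Msi2 peaks were described to show where the protein touched RNA. The authors' list of peaks found over all 5 CLIP libraries holds 4051 regions, and their 3' UTR list holds 2671 of them, 65.9% (95% Wilson interval 64.5 to 67.4%). Of the rest, 758 lay in protein-coding genes outside that list, 256 in no gene of the reference table, 164 in long non-coding RNA genes, 134 in small RNA genes, 51 in other genes or pseudogenes and 17 on the mitochondrial genome. By reads, 3' UTR peaks took 41.1 ± 7.22% (SD, n = 5 libraries) of the reads in peaks, with 29.6% in the library with undiluted RNase, 39.7 and 48.3% in those with the enzyme at 1 in 20 (low and high molecular weight complexes), 42.2% at 1 in 50 and 45.6% at 1 in 75. The 3' UTR peaks belonged to 1199 gene symbols, of which 1180 matched the count tables, and 671 of those genes had 1 peak, 509 at least 2 and 130 at least 5. Lnpep, an aminopeptidase, had the most, with 23 peaks between 17522111 and 17529767 on chromosome 17. It was followed by Prrg4 with 20 (chromosome 2, 104827410 to 104832574), the chloride transporter Clcn5 with 17 (chromosome X, 7153812 to 7159820) and Cd44 with 17 (chromosome 2, 102811382 to 102814309). The actin-binding caldesmon Cald1 had 15 (chromosome 6, 34773307 to 34775471), Emp1 had 14 (chromosome 6, 135380974 to 135383219) and moesin, Msn, which links actin to the membrane, had 14 (chromosome X, 96166567 to 96168561). Cdcp1, the connexin Gja1 and Lrrc58 had 13 each. By the authors' peak height, which counts overlapping reads over the 5 libraries, the tallest peaks of named nuclear genes in the 3' UTR list were those of the desaturase Scd2 (727, chromosome 19, 44304761 to 44306865), the chaperone Hspa8 (691, chromosome 9, 40803576 to 40803727, a region that also overlaps the small nucleolar RNA gene Snord14c), Lars2 (621, chromosome 9, 123461823 to 123462232) and Krt14 (460, chromosome 11, 100203130 to 100203411). The tallest region of the 3' UTR list itself was on the mitochondrial genome (827, 11113 to 12435, over the genes ND4 and ND5). Coordinates are mm10, and a library of a control antibody was not analysed here, so heights are not set against background.

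Genes with a 3' UTR peak were compared with genes in neither peak list, to ask whether bound RNAs changed when Msi2 was lowered. Their footprints were higher in the knockdown relative to unbound genes, by a median of 0.11 on the log2 scale (1146 and 7591 genes, adjusted p = 0.0160 over the 3 assays, camera). With an estimated correlation the adjusted p was 0.0893, which did not pass. Against unbound genes of the same expression the difference was 0.072, past the threshold of camera before adjustment. Of bound genes 16.6% were called higher and 8.55% lower in footprints, and of unbound genes 7.38% and 7.32%. These shares, and those of RNA and translational efficiency below, were not matched on expression. In RNA the difference was 0.08 (1166 and 9684 genes, camera p = 0.0389, adjusted p = 0.0584), which did not pass after adjustment, and the adjusted p was 0.428 with an estimated correlation. Of bound genes, 30.3% were called higher and 18.1% lower in RNA, against 20.8% and 22.3% of unbound genes. Without control replicate 2 the RNA difference was 0.064 and without knockdown replicate 1 it was 0.054, and against unbound genes of the same genomic span it was 0.011, none of which passed before adjustment either. It was larger against unbound genes of the same expression, at 0.174, and for genes with at least 2 peaks, at 0.126, both past that threshold before adjustment, and smaller for genes whose tallest peak was in the upper part of the heights, at 0.042, which did not pass before adjustment. The translational efficiency of bound genes differed from that of unbound genes by 0.00047 (adjusted p = 0.810). Against unbound genes of the same expression that difference was -0.10, past the threshold of camera before adjustment. Calls in translational efficiency were few, with 1 higher and 4 lower of 1164 bound genes (0.086 and 0.344%). Of 9391 unbound genes 11 were higher and 4 lower (0.117 and 0.043%). Of the called genes named above, Lpp (6 peaks), Mapk6 (4) and Zfp266 (2) were lower and Timp2 (2) was higher. By number of peaks, the median change was 0.04 in RNA and 0.05 in footprints for genes with 1 peak, and 0.34 and 0.17 for genes with 5 or more (129 and 130 genes), where 60 were called higher and 14 lower in RNA and 41 and 9 in footprints. In translational efficiency it was 0.016 with 1 peak, 0.083 with 3 to 4 and -0.065 with 5 or more. These classes were not matched on expression, genomic span or 3' UTR length. In RNA, all tested genes spanning over 100 kb had a median of 0.24.

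Among the genes with the most peaks, Prrg4 (0.63 ± 0.17), Clcn5 (0.72 ± 0.18), Cd44 (0.71 ± 0.11), Emp1 (0.50 ± 0.12), Cdcp1 (0.48 ± 0.14) and Lrrc58 (0.91 ± 0.29) rose in RNA, while Lnpep (0.24 ± 0.23), Cald1 (-0.12 ± 0.13), Msn (0.01 ± 0.15) and Gja1 (0.16 ± 0.12) did not pass. In footprints Clcn5 (0.64 ± 0.17), Cd44 (0.39 ± 0.14) and Emp1 (0.58 ± 0.13) rose and the other 7 did not pass. Lrrc58 lost its RNA call without control replicate 1 (adjusted p = 0.108) or knockdown replicate 1 (adjusted p = 0.0591), and Clcn5 lost its footprint call without control replicate 1 (adjusted p = 0.0547) or knockdown replicate 3 (adjusted p = 0.0873). The footprint call of Cd44 ended without control replicate 1 (adjusted p = 0.232) or 2 (adjusted p = 0.137) and knockdown replicate 1 (adjusted p = 0.155) or 3 (adjusted p = 0.256), and with upper-quartile factors (adjusted p = 0.0542), DESeq2 (adjusted p = 0.0750) or the span trend removed (adjusted p = 0.0678). None of the 10 passed in translational efficiency. Bound genes with small footprint p-values were, among those that rose, the scaffold protein Akap12 (1.91 ± 0.13, adjusted p = 1.31e-13), Thbs1 (2.02 ± 0.14), Itga2 (2.78 ± 0.19) and Plec (2.04 ± 0.15). Among those that fell, they were Lgals7 (-2.48 ± 0.16, adjusted p = 1.35e-12), the keratinocyte surface protein Ly6d (-1.55 ± 0.14), Spink5 (-1.63 ± 0.14), the amino acid transporter Slc7a5 (-1.12 ± 0.13) and Dbi (-1.13 ± 0.13). Itga2 has 6 peaks (chromosome 13, 114833101 to 114836030), Spink5 has 4 (chromosome 18, 44020838 to 44022099) and Thbs1 has 3 (chromosome 2, 118126077 to 118126879); Plec has 2, and Akap12, Lgals7, Ly6d, Slc7a5 and Dbi have 1 each.

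**Figure D4:**
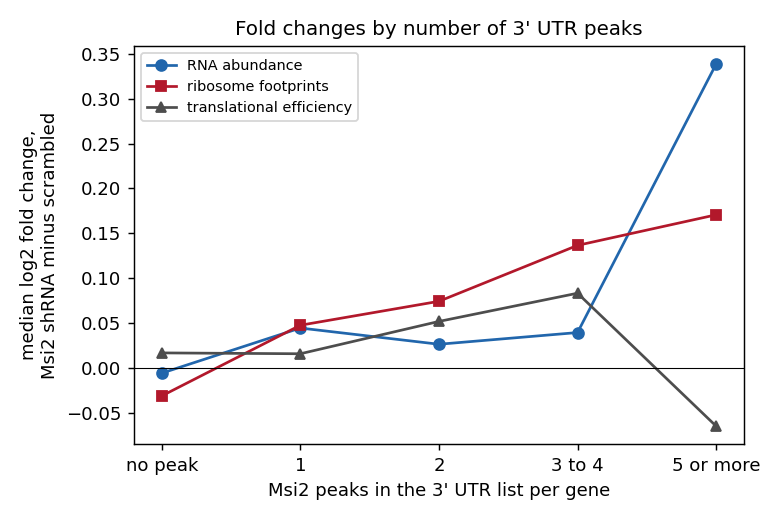
Median log2 fold change (vertical axis, knockdown minus control) of genes with no Msi2 peak, 1, 2, 3 to 4, or 5 or more peaks in the 3' UTR list (horizontal axis), in RNA, footprints and translational efficiency. In RNA the median of genes with 5 or more peaks is 0.34 and those of the lower classes are at or below 0.04, while in footprints it goes from 0.05 with 1 peak to 0.17. In translational efficiency it is 0.083 with 3 to 4 peaks and -0.065 with 5 or more. The classes are not matched on expression or genomic span.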

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

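The tests of feeder RNA, of the span trend, of the shallow footprint libraries, of peaks in the ATF4 list and of multiply aligned reads, and the use of the planned left-out libraries to test the ATF4 list, were chosen only after the results were seen. CLIP library 1, made with undiluted RNase, stood apart from the other 4 in 3 of 11 measures tested by Dixon's ratio (critical value 0.71), where chance alone marks about 1 in 20. It had a read in 1719 of the peaks (3970 to 4037 in the others) and in 36.8% of the 3' UTR peaks (98.1 to 99.7%). Both values go with its depth and with the peak filter: each listed region has a read in 4 or 5 libraries, so regions without one in this library had one in all the others. Of its reads in peaks, 7.08% lay in small RNA genes (2.30 to 3.64%). Its 6608 reads in peaks were the fewest of the 5 libraries. In the lines of the RNA table that belong to no gene, reads aligning to several places made up 21.8% in the knockdown, above the 15.2% of the control (exact permutation p = 0.1, the smallest possible).

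Other splits of the libraries were counted for each result. In RNA, 1 of 10 splits, the real one, had as many genes changed (4866, highest other 0), 2 of 10 had as many lists (17, highest other 18) and 2 of 10 as large a difference of peak genes (0.0808, highest other 0.0840). In footprints it was 1 of 10 for genes (1448, highest other 0), for lists (17, highest other 8) and for peak genes (0.106, highest other 0.0659). With 10 splits the share cannot fall below the threshold, so where the real split was highest these counts do not settle whether chance gave the values. In RNA, a split that mixed the groups and had 0 genes changed gave 18 lists and a difference of 0.0840. The count of RNA lists at the preset correlation and the RNA difference of peak genes thus did not stand out from regrouped libraries. For translational efficiency 6 of 100 splits had as many genes (22, highest other 4048), 58 as many lists (6, highest other 18) and all 100 as large a difference of peak genes (0.00047, highest other 0.21). For genes, the counts do not tell whether chance gave the value. The splits regrouped RNA and footprints separately, so real changes of either assay entered the ratio. The 5 splits with more genes all parted the RNA libraries by group, 1 of them the footprint libraries too. For lists, a split that parted neither assay by group and had 0 genes changed gave 16. The count of these lists at the preset correlation thus did not stand out from regrouped libraries. The real difference of peak genes was so near 0 that nearly any split exceeds it, so that count tells nothing about chance.

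The higher adhesion, matrix and basement membrane lists might reflect fibroblast RNA left from the feeder layer or the trend of the libraries with gene span. The fibroblast collagens Col1a1, Col1a2 and Col3a1 summed to 0.360 CPM in the knockdown, against a gain of 1335 CPM over the 16 called matrix genes, which rules out feeder RNA as the source of the gain. With the span trend removed, 10 of 10 camera tests of these lists passed at the preset correlation (largest adjusted p = 0.00549). That trend was thus not needed for the calls at this correlation. None of these lists passed with an estimated correlation even before the removal, so the test does not exclude a part played by the trend. An effect of lower Msi2 is left open beside an unintended target of the hairpin and a difference between the cultures, which were not tested.

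The lower ATF4 list might come from the span trend, from 1 deviating library, or from binding of Msi2 to these RNAs. With the trend removed its medians were -1.23 in RNA and -1.09 in footprints, against -1.20 and -1.12 before. In 12 of 12 fits that left out 1 library it passed camera at the preset correlation (highest median -1.0). The medians hardly moved, so neither the trend nor a single library was their source. With an estimated correlation the list did not pass even with all libraries (adjusted p = 0.229 in RNA and 0.154 in footprints, camera). Of its members 23.8% had a 3' UTR peak, against 27.8% of genes of the same expression (permutation p = 0.801), which does not tell whether binding plays a part. A difference of amino acid supply between the cultures, or an effect of the hairpin itself, was not tested and remains possible.

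The higher translational efficiency of ribosomal proteins and the respiratory chain could come from the span trend, from the shallow footprint libraries or from reads shared with pseudogenes. The medians were 0.25 and 0.33 with the trend removed (largest adjusted p = 2.00e-06), and 0.44 and 0.36 without the shallowest footprint library of each group. Removal of the trend also moved the median of all genes from 0.017 to 0.064, so a part of 0.25 and 0.33 is shared by all genes. Members without a named pseudogene had a median of 0.45 (41 genes) and members with one 0.33 (64 genes), a difference of 0.13 (95% bootstrap interval 0.01 to 0.20). That difference mixes the lists, since 61 of the 64 were ribosomal proteins and 27 of the 41 respiratory chain genes. Within the ribosomal proteins the medians were 0.52 without and 0.32 with a named pseudogene (interval of the difference -0.03 to 0.45), and within the respiratory chain 0.40 and 0.36 (-0.06 to 0.19). As the ratio was raised in members without a named pseudogene in both lists, shared reads with named pseudogenes are not the whole source. Only pseudogenes named after their gene were looked for, so members without one may still share reads with other copies. The span trend and the shallow libraries are not either. Neither an estimated correlation nor fry called these lists, and whether translation changed is left open.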

How the results depend on the processing

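The removal of the span trend, the span-matched genes, the fits without the shallowest footprint libraries, the block that joined RNA and footprint libraries and the left-out libraries for the correlation and for CLIP were chosen only after the results were seen, and the other settings beforehand. Counts of changed genes stayed within 1.5 times under other normalizations, filters and tests, and counts of called lists with DESeq2's size factors, the replicate block, the span trend removed and fry, except as follows; the cause was not tested unless named. Lists were not tested again under the other filters, upper-quartile factors, DESeq2's test or limma-voom. With a fold change minimum of 1, which keeps fewer genes by construction, the counts were 941 in RNA, 411 in footprints and 14 in translational efficiency, against 4866, 1448 and 22. DESeq2 called 808 genes in footprints. In translational efficiency the count was 124 without a filter, 14 at 10 CPM (fewer genes tested), 112 with DESeq2, 86 with limma-voom, 41 with the span trend removed and 13 without the shallowest footprint libraries. With an estimated correlation 0 lists were called in RNA, 0 in footprints and 0 in translational efficiency, where fry called 0 as well. The difference of peak genes in RNA was 0.046 with the span trend removed, 0.081 with an estimated correlation, 0.042 for genes whose tallest peak was in the upper part of the heights and 0.011 against span-matched genes; none of these passed. In translational efficiency it was -0.10 against genes of the same expression, past the threshold before adjustment. The correlation of RNA and footprint changes was 0.796 for genes of at least 5 log2 CPM, and 60.3% of the taller peaks were in the 3' UTR list.

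The replicate block left 3974 genes in RNA, 1494 in footprints and 3 in translational efficiency, with 18, 17 and 6 lists; the difference of peak genes was -0.0068 in translational efficiency and Itga2 stood at -0.014 there. Under this block Aldh1l2 (adjusted p = 0.0735), Trib3 (adjusted p = 0.141), Stc2 (adjusted p = 0.0855) and Pdgfra (adjusted p = 0.0564) were not called in RNA, nor Trib3 (adjusted p = 0.116) and Cd68 (adjusted p = 0.0507) in footprints. Deviations of same-numbered control and knockdown libraries correlated at 0.0573, -0.276 and -0.227 in RNA and 0.0503, 0.0291 and -0.0025 in footprints, and not every library correlated best with its own number, so the numbers were not taken as pairs. Same-numbered RNA and footprint libraries correlated at 0.152, 0.232 and 0.127 in the control and 0.170, 0.133 and 0.0039 in the knockdown, where all but knockdown replicate 3 matched their own number best. This hints that the numbers tie RNA to footprints. With a replicate block joining them, 353 genes were called in translational efficiency (246 higher, 107 lower), all 22 of the fit without it among them, and 9 lists. Msi2 passed there (-1.89, adjusted p = 0.0226), the difference of peak genes was -0.010 and Itga2 stood at -0.073.

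Leaving out each library in turn gave 3548 to 5486 genes in RNA, 842 to 1634 in footprints and 0 to 243 in translational efficiency, and 14 to 18, 15 to 17 and 6 to 10 lists. The difference of peak genes was 0.054 to 0.108 in RNA, 0.099 to 0.127 in footprints and -0.026 to 0.025 in translational efficiency. The correlation was 0.693 to 0.768 and the CLIP read share 39.3 to 44.0%. Signs turned within these ranges for Msn (-0.17 to 0.21) and Pmel (-0.12 to 0.40) in RNA, and for Kdr (-0.0071 to 0.23) and Cald1 (-0.045 to 0.12) in footprints. In translational efficiency they turned for Gja1 (-0.14 to 0.046), Akap12 (-0.053 to 0.15), Spink5 (-0.18 to 0.15), Lnpep (-0.32 to 0.028), Dbi (-0.044 to 0.31), Emp1 (-0.025 to 0.17), Itga2 (-0.55 to 0.39), Clcn5 (-0.24 to 0.10) and Cd68 (-0.85 to 0.12).

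Msn in RNA was -0.0046 without a filter, -0.0045 with DESeq2, -0.095 with limma-voom and -0.17 with the span trend removed. That removal also gave -0.021 for the ribosomal protein list in RNA, -0.018 for Cald1 in footprints, and 0.074 for Lnpep and 0.11 for Clcn5 in translational efficiency. Gja1 and Spink5 in translational efficiency were -0.037 and -0.042 with DESeq2's size factors, -0.052 and -0.057 with upper-quartile factors, -0.052 and -0.055 without a filter, -0.080 and -0.087 at 10 CPM, and -0.039 and -0.046 with DESeq2's test. The median of all genes in translational efficiency moved too, from 0.017 to -0.034 with DESeq2's size factors, -0.054 with upper-quartile factors, -0.090 without a filter, -0.064 at 10 CPM and -0.051 to -0.078 without single RNA libraries. Gja1 (0.013) and Spink5 (0.011) lay near 0 to begin with, so a shift of all genes of this size turns them without a change of their own. Itga2 there was -0.0062 at 10 CPM and -0.00083 with DESeq2's test. Lnpep was 0.011 with limma-voom and 0.043 without the shallowest footprint libraries, where Gja1 was -0.0062.

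Of 5436 values of 322 single genes and lists under these settings, 4981 kept direction and side of the threshold, 300 lost the call, 93 gained one and 62 turned, 49 of the latter in translational efficiency, where the shift of all genes adds to the turns. The tests of UAG density and of genes matched on 3' UTR length were not run, because no genome was used here. Changes of 0.5 on the log2 scale were recovered in 22.4% of simulated genes in footprints and 8.96% in translational efficiency. The simulation changed 200 genes, fewer than were called in the real footprint data, so the footprint share is not that of the real test.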

Other observations

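The comparison of list members with genes of the same expression in this part was chosen only after the results were seen. Msi2 peaks in 3' UTRs were more frequent than among equally expressed genes in 5 of 29 lists and rarer in 3. Of the basal keratinocyte genes 13 of 16 had one (81.3%, against 34.9% of genes of the same expression; permutation p adjusted over 29 lists = 0.00207). The same adjusted p was found for the junction genes, with 15 of 22 (68.2 against 32.2%), the actin and migration genes, with 17 of 29 (58.6 against 29.5%), and the RNA-binding proteins, with 14 of 29 (48.3 against 18.9%). Of the Musashi targets named in the literature 7 of 15 had a peak (46.7 against 16.1%, adjusted p = 0.00834). Peaks were rarer in ribosomal proteins, with 9 of 74 (12.2 against 40.1%, p = 1e-04, the smallest that 10000 permutations give), in the respiratory chain, with 1 of 30 (3.33 against 32.8%, adjusted p = 0.00207), and in replication-dependent histones, with 0 of 44 (against 29.0%, p = 1e-04). The other lists did not pass, among them focal adhesion (adjusted p = 0.120), stress keratins (adjusted p = 0.108), differentiated keratinocytes and secreted matrix (adjusted p = 0.263 each). The 3' UTR lengths of the lists were not measured here.

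Over all regions, the tallest peak lay on the mitochondrial genome (height 13806), where 17 peaks outside the 3' UTR list held 9.98% of the summed height. The 44 peaks on chromosome 17 between 39842993 and 39848848, a stretch that overlaps the ribosomal RNA gene Rn18s-rs5, held 5.78%. Not all lay in that gene, as the peak at 39842993 to 39843131 (height 580) was in no gene of the reference table. Counts of reads per 3' UTR peak had Spearman correlations of 0.194 to 0.628 between CLIP libraries. Fold changes went with the genomic span of the gene, with Spearman correlations of 0.239 in RNA, 0.112 in footprints and -0.21 in translational efficiency. Between single libraries, pairs of the same group reached 0.371 in RNA and 0.124 in footprints in absolute value. Pairs of different groups, knockdown minus control, lay between 0.0378 and 0.337 in RNA and between 0.0143 and 0.175 in footprints.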
